A study of Mus musculus with 8 samples.

How the data were processed

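RNA from the livers of 8 mice (4 control and 4 Mfn1 LKO) was measured on Illumina mouse bead arrays. RNA was extracted with a magnetic bead tissue kit and amplified into biotin-labelled RNA with the TotalPrep kit, per the labels' protocols. The authors deposited a linear signal intensity for each of 25697 probes in each array, with no detection p-values and no control probes, and the values were not background-subtracted. They also deposited log2 values of the same arrays. Every array of that table had the same distribution, within 0.0066 of quantile normalized log2 intensities without background subtraction, and each array's deposited log2 values were set against its own intensities to find this. The scanner software and the steps behind both tables are not given in the sources used here. No column of another sample was present in the tables used.

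Groups came from the sample titles. Animal numbers are not shared between groups, so that nothing pairs the samples, and the labels and tables name no slide, position or date.

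Intensities were background-corrected with limma's normexp (offset 50), quantile normalized between arrays and put on the log2 scale. The planned neqc correction needs detection p-values or control probes, and the planned fallback for their absence was used. Probes above their array's median in at least 4 of 8 arrays were kept, 12755 of 25697. Gene names came from GEO's platform annotation, with 23978 probes carrying 1 symbol, none several and 1719 unnamed here. Of the named probes 23962 matched a RefSeq gene table (assembly GRCm38.p6) by gene ID and 16 did not, and no symbol changed. Of 12003 named probes that were kept, the brightest over all 8 arrays was taken for each gene, which left 8815 genes. Groups were compared with lmFit and eBayes in limma 3.58.1 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over the genes tested and an adjusted p under 0.05 as the threshold. Fold changes are Mfn1 LKO over control, and the offset and the quantile step make those of dim genes smaller than the change in transcript.

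A set of 48 gene lists of liver pathways and cell type markers was fixed before the data were examined, as were the comparisons, the tests, the alternatives and the rule for named genes. The 43 lists with at least 5 measured genes were tested with limma's camera (preset correlation 0.01), adjusted over the 43 lists, and with camera with an estimated correlation and fry beside it. Camera compares a list's genes with the others, while fry tests whether a list's genes move 1 way and, in its mixed form, whether they move at all. Bile duct, adipocyte, exocrine pancreas and skeletal muscle markers and ketone body synthesis had under 5 genes and were not tested. A list score is the mean over members of the log2 signal minus its mean over the arrays, and was compared with an exact two-sided permutation test over 70 arrangements, which cannot go below p = 0.0286. After adjustment over the lists no score passed. The 8 lists at this smallest p had an adjusted exact permutation p of 0.154, and so few lists at the smallest p cannot pass. The median log2 fold change of all genes was -0.012, and lay between -0.024 and -0.0012 under other scalings.

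The rule for named genes took Mfn1, Mfn2 and Opa1, the 10 genes on each side with the largest change past the threshold or, where fewer passed, the smallest p, and 4 members with the smallest p of the first 8 lists past the test and of 6 lists set in advance. Gene models without a gene name proper, such as LOC or Gm followed by digits, were skipped. Members of other lists named in the text were chosen after their values were seen.

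The gene test was tried on simulated arrays with the 8815 genes' own means and SDs and 200 changed genes. Of 50 genes changed by 0.25 on the log2 scale 13 passed, of 50 changed by 0.5 45 passed, of 50 changed by 1 48 passed, and of 50 changed by 1.5 48 passed, with 5 false calls among 159. Benjamini-Hochberg adjustment is more lenient the more genes pass. Only Mfn1 passed in the livers, so the cut was stricter there and these shares do not carry over to the gene test. In 50 simulations with independent genes, a shift of 0.1 of the citrate cycle list was called in 50, and no shift was called in 0. Genes of a list are correlated in the livers, so this does not carry over to the list calls.

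The alternatives were no background correction, another offset, scaling to a common median or 75th percentile, cyclic loess, the deposited log2 values, other filters, other rules for several probes of a gene, limma-trend with robust estimation, array weights, a macrophage covariate, other list tests, a fold threshold of 1.5, and each array left out in turn. Those chosen after seeing the data are named with their results. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.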

Results

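Gene expression was measured on Illumina mouse bead arrays in the livers of 8 mice, 4 controls and 4 mice lacking Mfn1 in the liver (Mfn1 LKO). All had eaten a high fat diet for 8 weeks and were fasted for 6 hours. The labels name AlbCre, Cre recombinase under the albumin promoter, which deletes targeted genes in hepatocytes. Control titles carry this name too, while the control genotype is given as wildtype, so whether controls had Cre is unknown. If they had none, any effect of Cre itself is part of every difference below. Each array came from a different mouse (controls 641, 658, 661 and 663, Mfn1 LKO 637, 638, 651 and 701). The p-values of single genes and of the exact permutation tests measure the spread between these mice. Camera p-values with a preset correlation set a list's genes against the other genes. They do not measure how the list's score varies between mice. The arrays had median signals between 96.4 and 103.9, and the number of arrays limits the precision. The 95th percentile of the signal over the median was 9.02 ± 0.944 in controls and 9.10 ± 0.860 in Mfn1 LKO livers (SD, n = 4 each, exact permutation p = 0.943). Over all genes the correlation between arrays lay between 0.985 and 0.995, with a mean of 0.992 within groups and 0.991 between them.

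The first question was whether the targeted transcript was lower in the livers labelled Mfn1 LKO. Mfn1, an outer membrane GTPase of mitochondrial fusion, fell by 1.54 on the log2 scale (SE 0.064, 95% interval -1.68 to -1.40, adjusted p = 4.05e-06). Its log2 signal was 8.62 ± 0.057 in controls and 7.08 ± 0.11 in Mfn1 LKO livers (SD, n = 4 each), a level 2.91-fold higher in controls, and all 4 Mfn1 LKO mice lay below all 4 controls. A second Mfn1 probe gave -1.57. The third lay near the lowest signals of the array, between the 7.38th and 10.4th percentile of all probes, and gave 0.012. The files do not say where the probes lie relative to the deleted part of the gene. The related fusion genes did not pass the test. Mfn2 gave 0.025 (95% interval -0.084 to 0.13, adjusted p = 0.900) and Opa1, which fuses inner membranes, gave -0.12 (95% interval -0.28 to 0.034, adjusted p = 0.588). The Opa1 signal was low, 6.36 in controls and 6.23 in Mfn1 LKO livers where the lowest of all probes was 5.65. At such signals the interval does not bound the change in transcript. Its other probes gave -0.062 and -0.042.

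**Figure D1:**
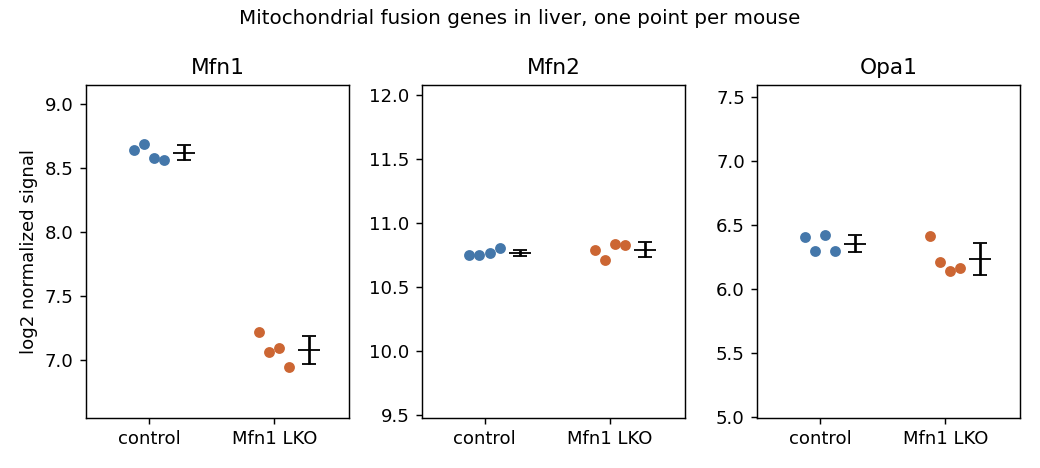
Log2 normalized signal of Mfn1, Mfn2 and Opa1 in 4 control and 4 Mfn1 LKO livers, 1 point per mouse, with the group mean and SD beside the points and the same length of scale in each panel. The Mfn1 means were 8.62 and 7.08, and the Mfn2 means 10.77 and 10.79.

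Mfn1 was the only gene of the 8815 tested that passed an adjusted p of 0.05 with limma. Ndufb5, a subunit of respiratory complex I, came next with a log2 fold change of 0.49 (SE 0.062, adjusted p = 0.0650). Ndufb5 lies beside the targeted gene, as measured gene 4 after Mfn1 on its chromosome, and the 3 measured genes between them, Gnb4, Actl6a and Mrpl47, gave -0.021, 0.25 and -0.061 (the adjusted p of Actl6a was 0.254, and all were named after their values were seen). Its adjusted p was 0.0404 without Mfn1 LKO mouse 701, 0.0442 with no filter and 0.0429 with array weights. At an unadjusted p under 0.05 there were 933 genes where chance gives 440.8, of which 516 were higher and 417 lower in Mfn1 LKO livers. In 539 genes (6.11%) the groups did not overlap, against 2.86% by chance. Both chance values are only means. At least 933 genes came from 2 of the 35 ways to split the 8 arrays into 4 and 4, the real one included. The highest other split gave 1218. Genes without overlap were not counted over the splits. The median SE of a log2 fold change was 0.067, and 99.2% of the 95% intervals lay within 1 log2 unit of 0. The lowest log2 signal was 5.65 and the median of all probes 6.02, so genes near these signals cannot fall by 1 unit. For such dim genes the intervals do not bound the change in transcript.

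Of the genes with a gene name proper, others with the smallest p on each side, none of them past the threshold, are given as values. On the higher side were Sdhd, an anchor subunit of succinate dehydrogenase (0.63), the ribosomal protein gene Rps3a1 (0.64), Ces1g, a carboxylesterase (0.48), the mitochondrial ribosomal protein gene Mrpl20 (0.45), Akr1e1 (0.42), Prep (0.35), Tcn2, a cobalamin carrier (0.28), Rwdd4a (0.25) and the complex I gene Ndufb2 (0.48), each with an adjusted p of 0.177. On the lower side were Slc38a2, an amino acid transporter (-0.49), Zfpm1 (-0.45), Eva1a (-0.42), Nr5a2, a nuclear receptor of bile acid and lipid genes (-0.29), Rtp3 (-0.27) and Tmem125 (-0.26), each with an adjusted p of 0.177. Jpt2 (-0.24) and Usp18 (-0.71) had an adjusted p of 0.206, and Luc7l3 (-0.23) one of 0.217. Not all probes of these genes went the same way. A second probe gave -0.030 for Prep, and 2 further probes gave 0.18 and 0.033 for Slc38a2. Counting only probes past the filter, 18 of all 64 named genes had 24 further probes, of which 6 had the opposite sign.

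The second question was whether gene groups of energy metabolism and other liver functions differed. Of 43 gene lists tested, 11 passed limma's camera with a preset correlation, 10 higher and 1 lower in Mfn1 LKO livers. None passed with an estimated correlation, where 3 had an unadjusted p under 0.05 and the lowest adjusted p was 0.562. None passed fry's directional test, where 7 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0634. By fry's mixed test, which takes changes in either direction and gives none, 10 passed. They were fusion and fission (which holds Mfn1, adjusted p = 1.34e-06), the citrate cycle and complexes II and III (0.00179 each), complex I, endoplasmic reticulum stress and autophagy (0.00899 each), mitochondrial chaperones (0.0322), and mitochondrial oxidation, cell cycle and proteasome (0.0359 each). Of the 35 ways to split the 8 arrays into 4 and 4, 13 gave at least 11 lists by camera, the real one included, so the number of lists did not stand apart from other groupings of these mice.

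Genes of the citrate cycle and the respiratory chain were higher on balance in Mfn1 LKO livers, by small amounts. Of 18 citrate cycle genes 14 were higher, with a mean log2 fold change of 0.13 and a median of 0.054 (camera adjusted p = 0.000567; adjusted p = 0.562 with an estimated correlation). None passed over all genes, and 6 passed when adjusted over the list alone. They included Sdhd, Mdh2, mitochondrial malate dehydrogenase (0.34), Dld, a subunit shared by 2-oxo acid dehydrogenases (0.45), and Idh2, mitochondrial isocitrate dehydrogenase (0.40). The complex IV list had a mean of 0.093 and a median of 0.070 with 13 of 19 genes higher (adjusted p = 0.00937; adjusted p = 0.562 with an estimated correlation). Its members Cox7a2 (0.30), Cox15 (0.20), Cox6c (0.27) and Cox7b (0.34) did not pass over the list alone. The complex I list had a mean of 0.070 and a median of 0.026 with 21 of 36 genes higher (adjusted p = 0.0200; adjusted p = 0.599 with an estimated correlation). Ndufb5 and Ndufb2 passed over the list alone, and Ndufb9 (0.54) and Ndufb10 (0.34) did not. Without Ndufb5, the neighbour of Mfn1, the complex I mean was 0.058 and the list did not pass (adjusted p = 0.0627). Complexes II and III, which share 3 genes with the citrate cycle list, had a mean of 0.11 and a median of 0.011 with 8 of 12 genes higher (adjusted p = 0.0494; adjusted p = 0.562 with an estimated correlation). ATP synthase genes did not pass (mean 0.089, median 0.043, 8 of 15 higher, adjusted p = 0.146).

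Taken as 1 pool, the 97 genes of these 5 lists had a mean log2 fold change of 0.088 and a median of 0.031, with 61 genes higher. All 22 genes with an unadjusted p under 0.05 were higher. The pool score, the mean of its members in each array, had an SD of 0.012 in controls and 0.021 in Mfn1 LKO livers, and all 4 Mfn1 LKO mice lay above all 4 controls (exact permutation p = 0.0286, the smallest that 4 against 4 can give). Without Ndufb5 the mean of the other 96 was 0.084, with the same exact p. The shift lay with the dimmer probes. It was 0.21 in the 33 genes of lowest signal, 0.029 in the middle 32 (exact permutation p = 0.171) and 0.024 in the brightest 32 (exact permutation p = 0.514). The pool was put together after the list results were seen. The macrophage marker mean was 0.27 higher in the same Mfn1 LKO livers. The call of complex I ended without control 658 (adjusted p = 0.136), Mfn1 LKO mouse 637 (0.0584) or 651 (0.0591). That of complexes II and III ended without control 641 (0.0683) or 658 (0.243), or without Mfn1 LKO mouse 637 (0.106), 651 (0.0671) or 701 (0.101), and the citrate cycle and complex IV passed whichever mouse was left out. Without Mfn1 LKO mice 651 and 637 together complex IV (0.0664), complex I (0.152) and complexes II and III (0.118) did not pass. With all mice complex I did not pass with array weights (0.0521) or a common 75th percentile (0.0548). Nor did complexes II and III with these (0.0864 and 0.0552), no background correction or the deposited values (0.0540 each), a common median (0.0732), cyclic loess (0.0713), the mean of probes (0.0722), offset 16 (0.0543) or the filter on all arrays (0.0629).

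**Figure D2:**
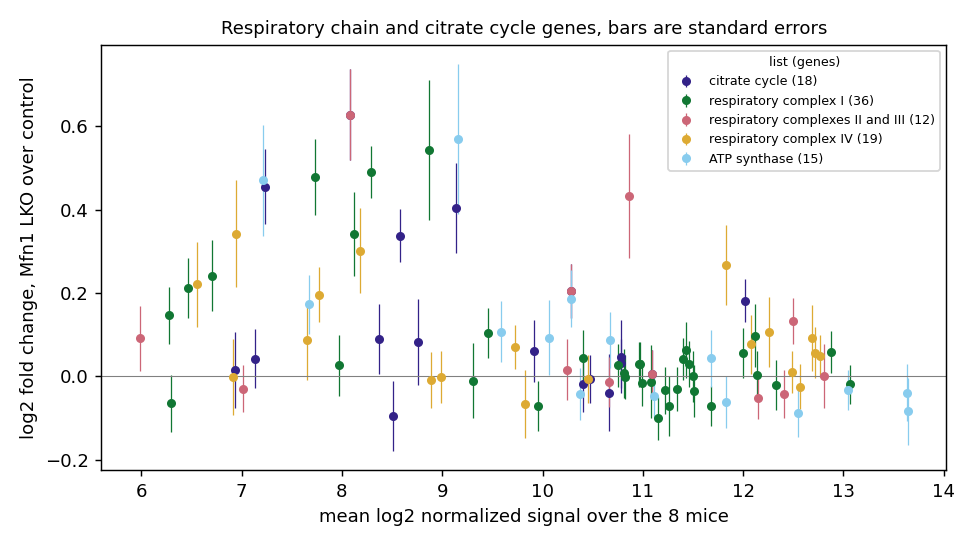
Log2 fold change of each respiratory chain and citrate cycle gene (Mfn1 LKO over control, with its standard error) against its mean log2 normalized signal over the 8 mice. Most changes above 0.2 lie at signals under 9.5, and the 32 brightest genes have a mean of 0.024.

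Genes of fatty acid oxidation were also higher on balance. Peroxisomal genes had a mean of 0.13 and a median of 0.048 with 17 of 21 higher (adjusted p = 0.00937; adjusted p = 0.688 with an estimated correlation). None passed over the list alone. The leading members were Ehhadh, the peroxisomal bifunctional enzyme (0.50), Pecr (0.56), Acot4 (0.34) and Pex19, an import factor of peroxisomal membrane proteins (0.16). Mitochondrial oxidation genes had a mean of 0.092 and a median of 0.043 with 12 of 19 higher (adjusted p = 0.0200; adjusted p = 0.709 with an estimated correlation). The 4 that passed over the list alone were Hadh (0.42), Hadhb (0.40), Eci2 (0.31) and Eci1 (0.19), enzymes of the beta-oxidation spiral and of unsaturated fatty acids. Both calls ended without control 658 (adjusted p = 0.0893 and 0.140) or without Mfn1 LKO mouse 637 (0.130 and 0.301), where the mean for mitochondrial oxidation was 0.057, or without 651 and 637 together (0.137 and 0.152), where that for peroxisomal genes was 0.082. With the macrophage marker mean as a covariate the means were 0.20 and 0.15. The macrophage marker mean was 0.27 higher in the same Mfn1 LKO livers.

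Among lipid and glucose synthesis lists, cholesterol synthesis had a mean of 0.14 and a median of 0.12 with 17 of 19 genes higher (adjusted p = 0.0200; adjusted p = 0.731 with an estimated correlation). Its members Idi1 (0.23), Tm7sf2 (0.16), Lss (0.24) and Msmo1 (0.38) did not pass over the list alone. The score varied more between Mfn1 LKO mice (SD 0.36) than the groups differed (exact permutation p = 0.486). The call ended without control 658 (adjusted p = 0.0884) or 661 (0.0973) or Mfn1 LKO mouse 651 (0.0563), and without Mfn1 LKO mouse 638 the mean was 0.0080 (0.671). The mean was 0.29 without mouse 637, 0.23 with array weights and 0.022 with the macrophage marker mean as a covariate (adjusted p = 0.288), and the call ended with the filter on all arrays (0.0575). The macrophage marker mean was 0.27 higher in the same Mfn1 LKO livers. Lipogenesis did not pass (mean 0.098, 17 of 28 higher, adjusted p = 0.0777). It did without control 663 (mean 0.15, adjusted p = 0.0112) or Mfn1 LKO mouse 637 (0.16, 0.00793) and with array weights (0.0353) or without mice 651 and 637 together (0.12, 0.00467), and the mean was 0.060 without mouse 651 and 0.045 with the macrophage covariate. Its leading members were Mogat1 (0.31), Mlxipl, which encodes the transcription factor ChREBP (-0.20), Fads2 (0.30) and Me1 (0.45). Gluconeogenesis did not pass either (mean 0.027, 8 of 14 higher, adjusted p = 0.636), with Pck1 at 0.47, Mdh1 at 0.29, Slc37a4 at 0.13 and Crtc2 at -0.11, and its mean lay between -0.0082 and 0.077 with 1 mouse left out.

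Macrophage markers were higher on balance in Mfn1 LKO livers. Of 20 markers of Kupffer cells, the resident liver macrophages, and other macrophages 17 were higher, with a mean and a median of 0.27 (adjusted p = 3.01e-06; adjusted p = 0.638 with an estimated correlation). Adgre1, an adhesion receptor of macrophages (0.75), Vsig4 (0.54), Clec4f (0.36) and Ctss (0.35) led the list, and none passed over the list alone. The marker score was -0.21, 0.11, -0.21 and -0.22 in controls 641, 658, 661 and 663, and -0.21, 0.043, 0.37 and 0.34 in Mfn1 LKO mice 637, 638, 651 and 701 (exact permutation p = 0.171). Neutrophil markers (mean 0.21, adjusted p = 0.105), lymphocyte markers (0.13, adjusted p = 0.0546), endothelial markers (0.050, adjusted p = 0.0971), red cell markers (0.10, adjusted p = 0.329) and stellate cell and matrix markers (0.041, adjusted p = 0.297) did not pass. Some did under other settings with all mice, neutrophil markers with no filter (adjusted p = 0.0423) or array weights (0.0367), and lymphocyte markers with a common median (0.0472) or offset 16 (mean 0.21, 0.0414). The lymphocyte mean was 0.054 with no filter (adjusted p = 0.436) and 0.047 with the macrophage covariate, the endothelial mean 0.028 with array weights, and the red cell mean 0.046 with no filter and 0.16 with offset 16. With the macrophage marker mean as a covariate the matrix mean was -0.17 (adjusted p = 5.28e-06) and the neutrophil mean -0.14. With 1 mouse left out the neutrophil mean lay between 0.026 and 0.41 and passed without control 658 (adjusted p = 0.0291) or Mfn1 LKO mouse 637 (0.0176). The lymphocyte mean lay between 0.051 and 0.19 and passed without control 661 (0.0201) or Mfn1 LKO mouse 637 (0.0320) or 638 (0.0200). The endothelial mean lay between 0.011 and 0.086 and passed without control 663 (0.0200) or Mfn1 LKO mouse 638 (0.00841), the matrix mean between -0.050 and 0.13 and passed without Mfn1 LKO mouse 637 (0.00438), and the red cell mean between 0.012 and 0.21. Without Mfn1 LKO mice 651 and 637 together neutrophil (0.49, adjusted p = 0.00248), lymphocyte (0.25, 0.0194) and red cell markers (0.35, 0.00256) passed.

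Interferon response genes were lower on balance in Mfn1 LKO livers, with a mean of -0.14, a median of -0.11 and 21 of 27 genes lower (adjusted p = 0.0200; adjusted p = 0.731 with an estimated correlation). Usp18, an interferon-induced protease, passed over the list alone, and its 3 probes gave -0.71, -0.78 and -0.45. Ifi27 (-0.92) and Mx2 (-0.21) did not, and Irgm1 was on the higher side (0.26, with a second probe at -0.18). The list score of Mfn1 LKO mouse 701 was 0.15, above all controls (exact permutation p = 0.229). The call ended without control 641 (adjusted p = 0.0906) or 658 (0.140) or without Mfn1 LKO mouse 637 (0.131) or 651 (0.176), or with array weights (0.110). Without 701 the mean was -0.22, and without 651 and 637 together it was -0.048 (adjusted p = 0.851). The macrophage marker mean was 0.27 higher in the same Mfn1 LKO livers, and the neutrophil marker mean 0.21.

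Of the remaining calls, cytosolic ribosome genes had a mean of 0.048 and a median of 0.032 with 39 of 56 higher (adjusted p = 0.0200; adjusted p = 0.731 with an estimated correlation). Rps3a1 passed over the list alone, and Rpl35a (0.37), Rpl29 (0.12) and Rpl4 (0.10) did not. The call ended without control 641 (adjusted p = 0.0544) or 661 (0.0647) or Mfn1 LKO mouse 651 (mean 0.026, 0.210) or 701 (mean 0.025, 0.303), and with the macrophage marker mean as a covariate the mean was -0.024. Without Mfn1 LKO mouse 637 it was 0.074. It did not pass with a common median (0.0745) or 75th percentile (mean 0.028, 0.0548). Cell cycle genes had a mean of 0.074 and a median of 0.040 with 14 of 20 higher (adjusted p = 0.0328; adjusted p = 0.709 with an estimated correlation). Ccnd1, which encodes cyclin D1, passed over the list alone (0.60, a gene named after its value was seen). The call ended without control 658 (0.323) or 661 (0.0727) or Mfn1 LKO mouse 638 (0.0608) or 701 (0.126), and with cyclic loess (0.0713), a common 75th percentile (0.0548) or the filter on all arrays (0.131). The macrophage marker mean was 0.27 higher in the same Mfn1 LKO livers.

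**Figure D3:**
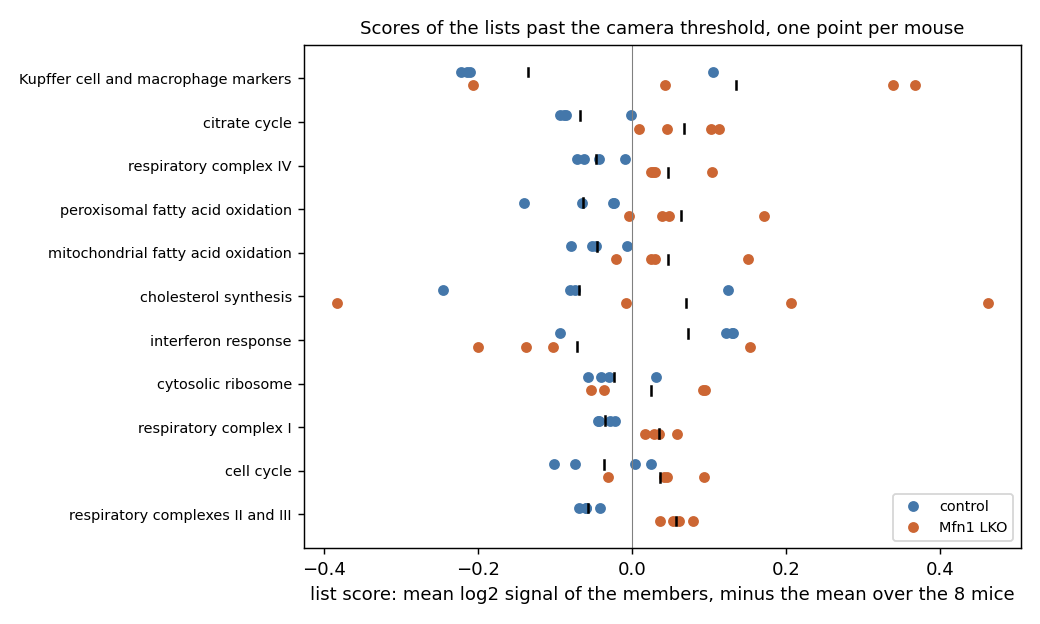
Score of each of the 11 lists past the camera threshold in each mouse (mean log2 signal of the members minus the mean over the 8 mice), with black bars for the group means. The groups do not overlap for the citrate cycle, respiratory complexes and peroxisomal oxidation lists (exact permutation p = 0.0286 each), and overlap for the others.

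The fusion and fission list did not pass (mean -0.071, 7 of 18 higher, adjusted p = 0.674). Besides Mfn1, Yme1l1, an inner membrane protease, passed over the list alone at 0.29, with a second probe at -0.029. Its unadjusted limma p of 0.00443 was adjusted with Mfn1 in the list. Because Mfn1 passes, that adjustment was more lenient for Yme1l1 than one without Mfn1. Inf2 gave 0.15 and Mff 0.17. Without Mfn1 the mean of the other 17 genes was 0.016. Mitochondrial ribosome genes (mean 0.025, adjusted p = 0.152), mitochondrial DNA maintenance genes (-0.033, adjusted p = 0.494), PPARA targets (0.090, adjusted p = 0.113), hepatocyte identity markers (0.045, adjusted p = 0.153) and insulin signalling genes (-0.032, adjusted p = 0.494) did not pass either. PPARA targets passed without control 663 (0.14, adjusted p = 0.0168) or Mfn1 LKO mouse 701 (0.14, 0.0348) and with the macrophage covariate (0.15, 0.00451), while their mean was 0.055 without control 658 and -0.0064 without mice 651 and 637. Mitochondrial ribosome genes passed without Mfn1 LKO mouse 651 (0.040, 0.0306) and with the macrophage covariate (0.050, 0.00451), and their mean was 0.0093 without mouse 637. With 1 mouse left out the means lay between 0.019 and 0.059 for hepatocyte identity, -0.056 and -0.015 for insulin signalling, and -0.053 and -0.024 for mitochondrial DNA maintenance.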

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

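The pooled respiratory test on second probes and the counts over splits of separated lists and of lists past fry's mixed test were tests chosen after the results were seen. The search for a sample far from the other 3 of its group covered 216 groups of 4 values, over 64 genes, 43 lists and 1 array measure, and 13 stood apart by Dixon's ratio (the gap over the group's range, at its 95% critical value), where chance gives about 1 in 20 groups (10.8). Mfn1 LKO mouse 651 accounted for 3 of them. It was low for Mdh1 (8.34 against 8.73 to 8.79 in the others, ratio 0.859), high for Yme1l1 (7.51 against 7.36 to 7.37, ratio 0.929), and high for the complex IV score (0.10 against 0.025 to 0.030, ratio 0.939). Mfn1 LKO mouse 701 was high for Nr5a2 (ratio 0.877) and for the acute phase score (0.42 against -0.12 to -0.075, ratio 0.915). Mouse 637 was low for Mff (ratio 0.847) and mouse 638 high for the mitochondrial chaperone score (ratio 0.864). Among controls, mouse 658 was high for the acute phase score (0.58 against -0.31 to -0.19, ratio 0.868) and for the macrophage score (0.11 against -0.22 to -0.21, ratio 0.963). Mouse 661 was low for the interferon score (-0.094 against 0.12 to 0.13, ratio 0.961). Mouse 663 was high for the citrate cycle score (-0.0010 against -0.094 to -0.086, ratio 0.913) and for Fads2 (ratio 0.836), and mouse 641 was low for Mogat1 (ratio 0.905).

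Chance could not be excluded for the number of genes or of lists past camera. As many genes as the real 1 came from 4 of the 35 splits of the 8 arrays, and the highest other split gave 10 genes, with control 658 beside Mfn1 LKO mice 638, 651 and 701. That split had 1218 genes at an unadjusted p under 0.05 against 933 in the real one. A grouping that crosses the groups thus gave more genes than the real one, and no test for a structure among the mice was run. As many lists as the real 11 came from 13 of the 35 splits, and the highest other split gave 15. The number of lists whose scores separate the groups completely was 8 in the real split and at most 5 in any other, so that 1 of 35 splits (0.0286) gave as many. One of the 8 is the fusion and fission list, which Mfn1 itself separates, and without Mfn1 the number was 7 against at most 5. By fry's mixed test 10 lists passed against at most 7 in any other split (1 of 35), and without Mfn1 9 against at most 7. These 2 counts, highest in the real split, were added after the first 2 had come out as chance. The number of genes at an unadjusted p under 0.05 was a further count, reached by 2 of the 35 splits. Even without it, the smallest share that 35 splits can give is 0.114 when multiplied by the other 4 counts. The splits are thus too few to decide over the counts together.

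The higher respiratory chain and citrate cycle genes were weighed against 4 technical explanations. A single array is argued against, since at least 88.8% of the mean shift stayed whichever array was left out. A trend with signal level shared by all genes is argued against, since random lists matched on signal had a mean of -0.0039, against 0.088 in the pool. The pool's place at the 100th percentile of 10000 such lists (95th percentile 0.020) adds little. Most of its lists had already passed camera, which sets genes against other genes, and the random genes were drawn independently. Within the pool the shift was 0.21 in the 33 genes of lowest signal, 0.029 in the middle 32 and 0.024 in the brightest 32. Macrophage content is argued against, since 89.3% of the shift stayed with the marker mean as a covariate (0.079, SE 0.014). Effects of single probes stay open. In 18 pool genes with a second probe, that probe gave a mean of 0.062 (SE over genes 0.034) and the chosen, brighter probe 0.013 (SE over genes 0.020). Neither passed 2 SE, and these SEs do not measure the spread between mice. The chosen probes of the 18 genes also held little of the pool's shift of 0.088, so they cannot show whether single probes made it. Loss of Mfn1 is among the explanations left open, as are Cre itself, RNA integrity and probe position, for which the tables hold no measure.

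For the higher macrophage markers, a single array is argued against, since at least 71.5% of the shift stayed. Leaving out 1 array cannot show a grouping of mice that crosses the groups. The marker scores of control 658 and Mfn1 LKO mice 638, 651 and 701 were 0.043 to 0.37. Those of controls 641, 661 and 663 and Mfn1 LKO mouse 637 were -0.22 to -0.21. The same split of the arrays gave 10 genes past the threshold, and neutrophil scores parted the mice in the same way. Whether the markers follow loss of Mfn1 or this grouping was not tested and stays open. A lower share of hepatocytes would raise endothelial and matrix markers alike, and the macrophage shift exceeded their mean by 0.23 (exact permutation p = 0.0571), which leaves it open. For the lower interferon genes at least 70.5% of the shift stayed without any 1 array. Apart from the share of hepatocytes, no biological explanation of either was tested, and the exact permutation tests of both scores missed the threshold.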

How the results depend on the processing

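The alternatives with offset 16, a common 75th percentile, a macrophage covariate, a filter above the median in all 8 arrays, without Mfn1 LKO mice 651 and 637 together, and fry's mixed test were chosen after seeing the data; the others were planned. Mfn1 stayed lower and past the threshold in all 22 alternatives, from -1.83 (offset 16) to -1.33 (no background correction), and from -1.59 to -1.51 with 1 mouse left out (highest adjusted p = 0.000166). No value of the other 63 named genes changed sign. Apart from Mfn2 and Opa1 they were named for small p on the same arrays, which made this likely in advance. Where all probes were tested, the probe with the smallest p stood for its gene. The 6 further probes of opposite sign thus do not show there. The count of genes was 2 with no filter or with array weights (Mfn1 and Ndufb5), 2 without mice 651 and 637 (Mfn1 and Clec4a3), and 1 to 3 with 1 mouse left out, the 3 without mouse 701 being Mfn1, Ndufb5 and Bhmt. The count of lists, 11, was 7 with a common 75th percentile, 17 with the macrophage covariate, 0 with an estimated correlation, 0 by fry's directional test, 10 by its mixed test, and 6 (without control 658) to 15 (without control 663) with 1 mouse left out. The citrate cycle passed in 21 of 21 camera alternatives and macrophage markers in 20 of 20, complex IV in 20, peroxisomal and mitochondrial oxidation in 18 each, complex I, cholesterol and interferon in 15 each, ribosome and cell cycle in 14 each, and complexes II and III in 6. Of 899 list values 53 lost and 33 gained a call. A further 60, of 17 lists, changed sign, 5 of them with a call on either side. The cause was not tested. The mean for male-biased genes was 0.0061 without background correction and with deposited values, 0.0043 with a common median, 0.011 with cyclic loess, 0.021 with the mean of probes, 0.034 with array weights and 0.010 above the median in all arrays. That for amino acid catabolism was 0.0037 with a common median and 0.013 with cyclic loess, that for periportal markers 0.0074 with cyclic loess and 0.0072 with offset 16, that for female-biased genes -0.0061 with array weights, and that for autophagy -0.0032 with a common 75th percentile. With the macrophage covariate the means were 0.0094 for mitochondrial DNA maintenance, 0.12 for amino acid catabolism, -0.045 for NRF2, 0.060 for cytochrome P450, -0.024 for ribosome, -0.23 for acute phase, 0.0059 for clock, 0.19 for male-biased, -0.17 for matrix, -0.14 for neutrophil, 0.083 for pericentral and 0.084 for periportal genes. Without mice 651 and 637 they were -0.0064 for PPARA targets, 0.029 for amino acid catabolism, -0.0063 for autophagy, 0.045 for male-biased, -0.0071 for female-biased, 0.0042 for pericentral and 0.0099 for periportal genes. With 1 mouse left out, means ran from -0.031 to 0.12 for NRF2, -0.077 to 0.27 for acute phase, -0.074 to 0.087 for amino acid catabolism, -0.0065 to 0.081 for bile acid, -0.041 to 0.0073 for clock, -0.052 to 0.18 for female-biased, -0.0082 to 0.077 for gluconeogenesis, -0.16 to 0.21 for male-biased, -0.0037 to 0.023 for autophagy, -0.093 to 0.055 for pericentral, -0.058 to 0.055 for periportal, -0.050 to 0.13 for matrix and -0.13 to 0.0064 for cytochrome P450 genes. A slide block was not run, since no slides are named, and testing all probes gave no list test. Dim probes limit the rest: signals near the lowest of an array hold little beyond background.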

Other observations

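Of the tests in this part, that on Ndufb5, that on second probes of genes with an unadjusted p under 0.05 and the search over pairs of lists were chosen after the results were seen. The gene names in the next sentences were too. Several further groups held members that passed over their list alone although the list did not pass by camera. Mitochondrial chaperones and proteases (mean 0.093, camera adjusted p = 0.0937) separated the groups (exact permutation p = 0.0286), with Hspe1 and Hspd1, the mitochondrial chaperonin pair, at 0.51 and 0.27, the processing peptidase subunit Pmpcb at 0.52, Yme1l1 at 0.29 and the import receptor Tomm70a at 0.23. This list passed with a common median (0.11, adjusted p = 0.0444), and gave 0.059 with the mean of a gene's probes (adjusted p = 0.478). In the mitophagy and autophagy list (mean 0.0092, median -0.056, adjusted p = 0.809) Map1lc3b (0.43), Atg3 (0.26) and the lysosomal protease Ctsb (0.32) were on the higher side. The endoplasmic reticulum stress list (mean -0.070, adjusted p = 0.0633) had Calr, the chaperone calreticulin, at -0.34. It passed with no filter (adjusted p = 0.0257), without control 663 (-0.10, 0.00354) or Mfn1 LKO mouse 638 (-0.096, 0.0125) and with the macrophage covariate (-0.11, 0.0109), and its mean was -0.043 without control 658. Aldh1a1 (0.43) and Glul, glutamine synthetase (0.48), stood out among pericentral hepatocyte markers, whose mean was -0.031 (adjusted p = 0.814). Bhmt (0.85) did so among serine, glycine and one-carbon genes (0.046, adjusted p = 0.543), Baat, which conjugates bile acids (0.48), among bile acid genes (0.031, median -0.015, adjusted p = 0.877), and Bckdhb (0.34) and Tdo2 (0.46) among genes of amino acid catabolism (-0.0047, with the camera direction upward, adjusted p = 0.809). With the macrophage covariate one-carbon genes (0.16, adjusted p = 0.00843) and amino acid catabolism (0.12, 0.00537) passed, and the latter did without Mfn1 LKO mouse 651 (0.087, 0.0306). With 1 mouse left out the mean lay between 0.0040 and 0.11 for one-carbon genes, -0.0065 and 0.081 for bile acid genes, and -0.074 and 0.087 for amino acid catabolism. Macrophage markers were 0.27 higher in the same livers.

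The other lists did not pass. They were glycolysis and glycogen (mean -0.045, adjusted p = 0.763), proteasome (-0.019, 0.556), circadian clock (-0.019, 0.877), NRF2 and glutathione (0.052, 0.342), ATF4 targets (-0.065, 0.494), xenobiotic cytochrome P450 genes (-0.049, 0.877), acute phase genes (0.056, 0.809), immediate early genes (-0.099, 0.460), periportal markers (-0.0082, with the camera direction upward, 0.608), male-biased genes (-0.0070, 0.942) and female-biased genes (0.063, 0.300). Acute phase genes passed without control 658 (0.27, adjusted p = 0.00916) and, in the other direction, with the macrophage covariate (-0.23, 0.00537), with which immediate early genes (-0.20, 0.00843) and ATF4 targets (-0.13, 0.0419) passed too. With 1 mouse left out the mean lay between -0.032 and -0.00080 for proteasome, -0.058 and -0.027 for glycolysis, -0.10 and -0.037 for ATF4 and -0.14 and -0.043 for immediate early genes, and the other lists of this paragraph had means on both sides of 0. Some of these varied widely between mice of 1 group: the SD of the male-biased score was 0.49 in controls and 0.34 in Mfn1 LKO livers, and that of the acute phase score 0.41 and 0.26. Over all 903 pairs of lists, scores centred within groups were correlated over the 8 mice with a permutation p under 0.05 in 85 pairs. None passed adjustment over the pairs (lowest adjusted p = 0.409), so no pair is singled out. With 576 arrangements the permutation p cannot go below 0.0017, and a few pairs alone could not pass however strong. The adjustment thus cannot show that lists are unrelated.

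A linked region from the targeted allele could leave differences in genes beside Mfn1. Of its 40 measured neighbours in RefSeq gene order, 5 had an unadjusted p under 0.05, at the 59.8th percentile of 7951 equally sized runs elsewhere (95th percentile 8). This argues against a region in which many genes differ. Such a count cannot show a region in which only a few genes differ. Ndufb5, with the second smallest p of all genes, is nevertheless among the nearest. Of the 9 other nearest genes 1 had an unadjusted p under 0.05, at the 36.6th percentile of equal runs, and this does not exclude a local effect of the allele, or of sequence carried with it, on Ndufb5 alone. Whether the higher Ndufb5 signal follows from loss of Mfn1 or from its place beside Mfn1 cannot be told apart, since each Mfn1 LKO liver has both.

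Effects of single probes could also produce genes with small p. Of 253 genes with an unadjusted p under 0.05 and a second probe past the filter, the second probe kept the direction in 68.0% (exact binomial 95% interval 61.9 to 73.7%), and in 2036 genes with a larger p in 62.8% (exact p of the difference 0.112). In the 253 genes the shifts of chosen and second probes had a correlation of 0.56. The median size of the second probes' shift was 33.3% of that of the chosen probes. The genes were picked by the chosen probe's p, and the second probe is the dimmer one. Both make this share smaller, so it does not tell of probe effects. Probe effects stay open.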
